A study of Mus musculus with 2 samples.

How the data were processed

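Gene expression was measured on 1 Affymetrix array per genotype, from total RNA of mouse embryonic fibroblasts (cells grown out of dissociated embryos) taken at embryonic day 12.5 and kept to passage 1. The labels give C57BL/6 as the strain of both cultures. Each array held biotin-labelled cRNA, per the labels' protocols. The authors deposited 1 table of intensity values, a linear signal for each of 45101 probe sets on each array. The submitters' processing notes name Affymetrix Expression Console and MAS5, which summarises the probe pairs of a probe set into 1 signal, without versions. The step that scaled the arrays is not given in the sources used here. The values themselves show that, with 2% of probe sets trimmed at each end, the mean signal of each array was 500.0, and they were used at that scale. No detection calls and no scanner files were used here, so no presence call stands behind any signal.

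Signals were taken to log2. The 64 control probe sets were left out, which left 45037. Of these, 34945 carried 1 gene symbol, 932 carried several and 9160 had none listed in the platform annotation. Symbols were updated through a RefSeq gene table of the assembly GRCm38.p6, in which 34741 of the probe sets with 1 symbol found a match; the others kept the symbol of the annotation. That table served only for names and for the order of genes along chromosomes, since the sources used here name no build for the array. Probe sets with several symbols or none gave no gene a value. A gene was represented by its probe set of highest mean log2 signal over both arrays, which gave 18193 genes.

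The floor was the higher of the 2 arrays' median signals over probe sets other than controls, 94.8. A signal below the floor was raised to it, and the fold is then a bound, written "at least". A gene was called measured when its probe set lay above the floor on at least 1 array, which held for 11408 genes. Differences are log2 ratios, Phc2 L307R minus wild type. With 1 array per genotype there is no replicate error, so no gene was tested for significance between the genotypes and no p-value was computed. Genes were counted by size alone, at a threshold of 2-fold. The only error available is technical: the SD of the log2 ratio between probe sets of 1 gene was 0.32 over 5460 genes with at least 2 measured probe sets. Across the 10703 genes above the floor on both arrays, the SD of the log2 ratio was also 0.32. The 2 values are alike in size but come from different sets. The first includes dimmer probe sets and values raised to the floor, while the second takes 1 probe set per gene, above the floor on both arrays. They allow only a rough comparison of the spread between genes with the disagreement between probe sets.

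The gene lists, the rule for named genes and all but the last of the alternative settings were fixed before the data were examined. There were 54 lists, 38 of pathways, complexes and gene families and 16 of cell type markers, with 1065 genes in all, written from general knowledge. For each list, the median log2 ratio of the measured members was placed among the medians of 10000 random lists of the same size, matched on mean log2 signal in 20 bins, as a description of these 2 arrays. A list was called above or below when its median lay beyond the 97.5th or the 2.5th percentile. The named genes were Phc2 with every probe set, then the 12 genes of highest and the 12 of lowest log2 ratio among measured genes whose measured probe sets all differed in the same direction, without clone names and sex-specific genes. For each list described, up to 4 measured members of largest absolute log2 ratio were named, and any member of the Hox, PRC1, PRC2 and Ink4a lists. A gene named outside this rule is said to have been chosen after its values were seen.

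The alternatives were quantile normalization, a loess of the log2 ratio on the mean signal (span 0.4, 3 iterations), centring on the median of measured genes, floors at the 40th and 60th percentiles, no floor, the floor's value as a pseudocount, the mean over a gene's measured probe sets, the removal of probe sets with the suffixes _x_at and _s_at (which mark probes that can bind several transcripts), and thresholds of 1.5-fold and 3-fold. The removal of the 100 measured genes on each side of Phc2 was added after the data were seen.

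The calculations were tested on simulated arrays, made from the mean signals of both arrays and their log2 ratios reshuffled among probe sets of similar signal, with known differences planted. For the comparison of Phc2 L307R with wild type, over 11400 genes, 86% of 50 genes with a planted fold of 2.5 passed the 2-fold threshold, as did 94% of 50 at 3-fold, 100% of 50 at 4-fold and 96% of 50 at 6-fold. Over 11395 genes without planted differences, 3% of 200 random lists of 16 unchanged genes lay outside the range. Of 200 such lists shifted by 0.5 on the log2 scale, 100% lay above it. These lists were drawn from the shuffled genes themselves, so both results check the calculation and not how genes of a real list vary together. The simulation gives no estimate of how many real 2-fold differences are false. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.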

Results

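Phc2 is a subunit of Polycomb repressive complex 1 (PRC1), which keeps developmental genes silent. L307R is a missense change in its SAM domain, the part through which Phc2 molecules polymerise. The comparison asks how the expression of Polycomb targets and of other genes differs between wild-type embryonic fibroblasts and fibroblasts homozygous for this change. There were 2 arrays, 1 per genotype, and the labels give the same strain, embryonic day and passage for both. The number of arrays limits the precision: no value below has a replicate, and each difference is one between 2 cultures. The arrays had close medians, 94.8 for wild type and 94.3 for Phc2 L307R, while the brightest probe set reached 33491 and 43746. The Spearman correlation between the arrays was 0.955 over 45037 probe sets. The signal at the 3' end of Gapdh over that at its 5' end, a measure of RNA integrity, was 0.791 in wild type and 0.721 in Phc2 L307R, and that of Actb was 1.15 and 1.14. Eif2s3y, Kdm5d and Uty, all on the Y chromosome, were measured on both arrays at log2 ratios of -0.42, -0.23 and 0.22, and Xist lay below the floor on both.

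Phc2 itself had a signal of 3184 in wild type and 4079 in Phc2 L307R at probe set 1416048_at, a log2 ratio of 0.36. At its other probe set, 1437239_x_at, the signals were 3145 and 3103, a log2 ratio of -0.02. The mean of both was 0.17. A missense change need not alter the amount of the transcript, so these values check nothing about the labels.

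Of 11408 measured genes, 66 were at least 2-fold higher in Phc2 L307R and 61 at least 2-fold lower, together 1.11%. The median log2 ratio of all measured genes was 0.06, and with ratios centred on it the counts were 47 higher and 75 lower, which turned the share of higher genes from 52.0% to 38.5%. The strongest difference was in Cap1, which encodes an actin-binding, adenylyl cyclase-associated protein: its signal was 7207 in wild type and 310.1 in Phc2 L307R, 23.2-fold lower, and its second probe set was 31.5-fold lower. Among the lower genes that the naming rule takes, which leaves out clone names, the next were Kcnj11, a subunit of the ATP-sensitive potassium channel (5.76-fold lower, from 3158 to 548.3), and Tnfrsf11b, the decoy receptor osteoprotegerin (3.85-fold lower). A further probe set of Tnfrsf11b had a log2 ratio of only -0.21. Efcab3 was at least 3.06-fold lower, Mrpl33 2.93-fold, Rpgrip1 2.87-fold, Tnfaip6, a hyaluronan-binding protein of inflamed tissue, 2.80-fold, Dmxl1 2.78-fold, Lrrn1 2.71-fold, Aunip at least 2.67-fold, Nwd1 2.56-fold and Cip2a, an inhibitor of protein phosphatase 2A, 2.504-fold. Every further probe set of Kcnj11, Mrpl33, Rpgrip1, Lrrn1 and Cip2a lay below the floor on both arrays, so each of these values rests on 1 probe set.

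Among the genes higher in Phc2 L307R, several are known from skeletal tissue. Ibsp, the bone sialoprotein, was 4.36-fold higher (228.8 to 997.6), and its second probe set at least 5.05-fold. Cnmd, the cartilage protein chondromodulin, was at least 3.23-fold higher, and Matn1, a cartilage matrix protein, at least 3.07-fold. Pdpn, the membrane glycoprotein podoplanin, was 3.16-fold higher (983.7 to 3107) and the secreted C1qtnf12 3.12-fold. Zfp593 was 4.72-fold higher at an _x_at probe set, while its other probe set had a log2 ratio of 0.03. Vegfd, a growth factor for lymphatic vessels, was 2.90-fold higher at 1 probe set and had log2 ratios of 0.02 and 0.39 at the others. Tspan11 was 3.27-fold higher, the co-repressor Tle6 at least 3.09-fold, Nrn1 2.85-fold, Trnp1 2.81-fold and Pianp at least 2.79-fold. The further probe sets of Tspan11, Trnp1 and Pianp all lay below the floor on both arrays.

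How far single genes can be trusted varied. Of the 127 genes with a 2-fold difference, 81 rested on 1 measured probe set. In the other 46, all measured probe sets differed in the same direction in 27 and in both directions in 19. In 5 genes, each with at least 2 measured probe sets, every one of these differed at least 2-fold: Ibsp, Eln (elastin, 2.07-fold at its main probe set) and Stmn2 (a neuronal regulator of microtubules, 2.02-fold) were higher, and Cap1 and Rgs17 (a regulator of G protein signalling, 2.34-fold) were lower. Rgs17 lies outside the rule for named genes and was chosen after its values were seen. Of the higher genes, 18 lay below the floor in wild type, and of the lower genes 7 lay below it in Phc2 L307R. The counts depend on the floor: without one they were 159 and 122, and with a floor at the 60th percentile 27 and 35.

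**Figure D1:**
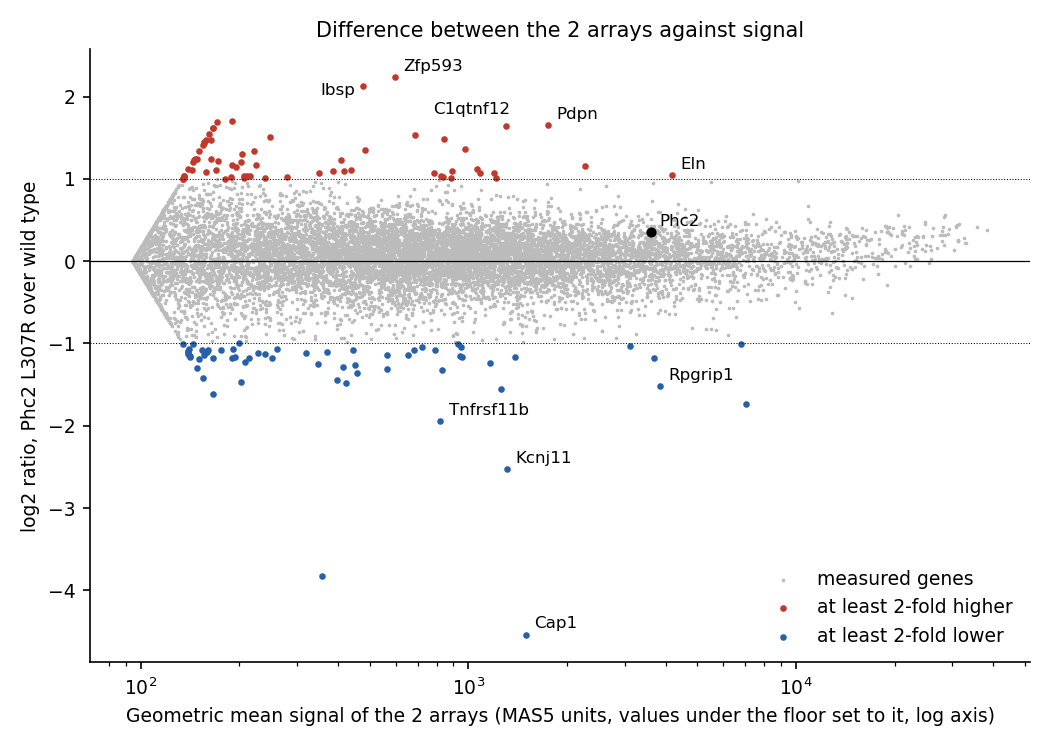
Each point is 1 of 11408 measured genes, with the geometric mean of its signals on the 2 arrays on the x axis (MAS5 units, log scale, signals under the floor set to it) and the log2 ratio of Phc2 L307R over wild type on the y axis. Red and blue points are the 66 genes at least 2-fold higher and the 61 at least 2-fold lower, Cap1 lies lowest at -4.54, and the black point is Phc2 at 0.36.

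Genes with a 2-fold difference were frequent near Phc2 on its chromosome, mostly to 1 side of it. Of the 100 measured genes on each side of it, 10 differed at least 2-fold, 7 higher and 3 lower. Around 7032 other genes whose neighbours share none with these, the median count was 2 and the highest 7. The neighbours of these other genes overlap widely with each other, so they hold far fewer separate counts than 7032. The higher genes were Zfp593, Matn1, Trnp1, Sfn (at least 2.67-fold), Pafah2 (2.15-fold), Iqcc (2.05-fold) and Laptm5 (2.005-fold). The lower ones were Cap1, 47 measured genes from Phc2, Ptp4a2 and Aunip. Ptp4a2, Pafah2 and Iqcc lie outside the rule for named genes and were chosen after their values were seen. Of the 10, 9 lay on the side of higher position and only Cap1 on the other. Beyond the 100 measured genes, 5 more on that side were at least 2-fold higher (Pdpn, Znf41-ps, Fndc10, Mxra8 and C1qtnf12), and on the other side Alg6 and Rbm12b2 were at least 2-fold lower. Of these 7, all but Pdpn and C1qtnf12 lie outside the rule and were chosen after their values were seen. In all, 14 of the 251 measured genes on the side of higher position differed at least 2-fold and 3 of the 440 on the other. The 4 probe sets of Ptp4a2, a protein tyrosine phosphatase, ranged from a log2 ratio of -1.74 to 1.07. Without these 200 genes, which leaves in the 7 farther out, 59 genes were at least 2-fold higher and 58 lower.

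**Figure D2:**
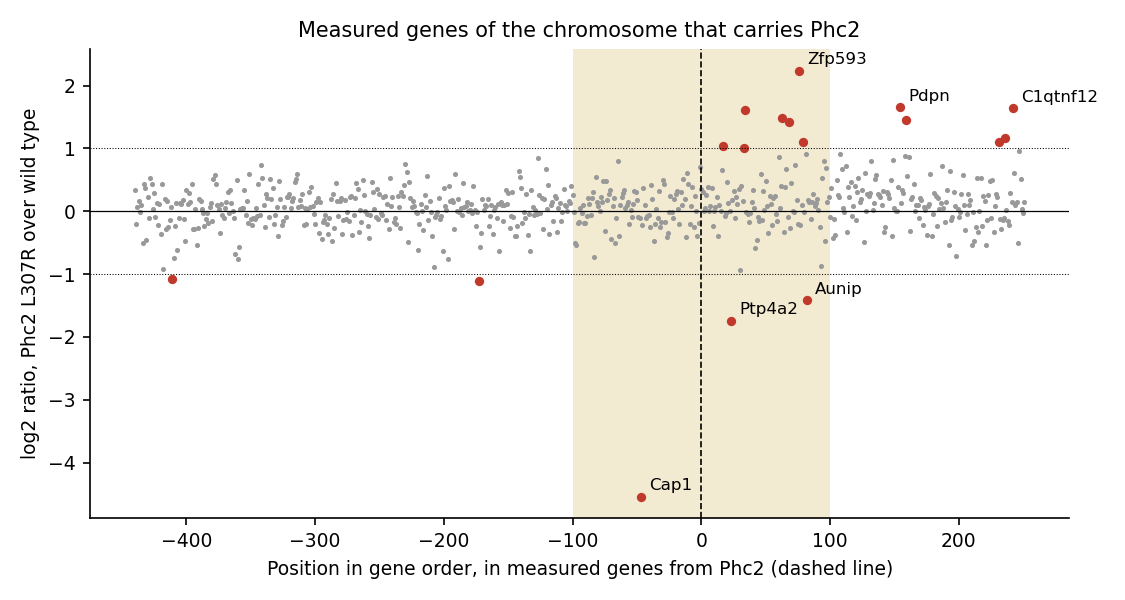
Each point is a measured gene on the chromosome of Phc2, placed by its order along it (x axis, in measured genes from Phc2, at the dashed line), with its log2 ratio of Phc2 L307R over wild type on the y axis. Red points differ at least 2-fold, and the shaded band holds the 100 measured genes on each side of Phc2, 10 of them red, 9 to the right of Phc2.

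The Hox genes, transcription factors of the body axis and the classical targets of Polycomb, differed little as a family. Of 33 Hox genes with a probe set, 28 were measured, 12 with a log2 ratio above 0 and 16 below. Their median log2 ratio was -0.05, at percentile 6.06 of matched random lists, and it was 0.00 with the mean over probe sets and 0.02 without _x_at and _s_at probe sets. Only Hoxa7 differed at least 2-fold, with signals of 84 in wild type and 195 in Phc2 L307R, at a log2 ratio of at least 1.04. Hoxd8, Hoxd13, Hoxc13 and Hoxd9 followed at 0.68, 0.65, at least 0.65 and 0.53, and the lowest were Hoxa2 at -0.62 and Hoxa5 at -0.53. The second probe sets of Hoxd13 and Hoxa5 gave 0.71 and -0.55, and that of Hoxd8 gave -0.15.

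Over all measured Hox genes, the log2 ratio tended to rise with the paralog number, which gives the position of a gene within its cluster. Within single clusters this was clear for Hox C and, by rank, for Hox A. In groups 1 to 4, at the 3' end of the clusters, the median was -0.31 over 8 measured genes, at percentile 0.58. In groups 5 to 8 it was -0.19 (8 genes, percentile 3.60), and in groups 9 to 13, at the 5' end, it was 0.17 (12 genes, percentile 85.7). Across the 28 genes, which are not independent replicates, the paralog number and the log2 ratio had a Spearman correlation of 0.64 and a Pearson correlation of 0.59. The Pearson correlation was 0.55 without Hoxa2 and Hoxa13. These 2 were taken by list order among the genes tied as farthest from the median number. Hoxb2, Hoxc13 and Hoxd13, as far from it, stayed in, so this is a weak check on the end genes. The Spearman correlation was 0.53 to 0.68 under the alternatives. Within clusters it was 0.78 for Hox A (9 genes), 0.82 for Hox C (7 genes), 0.20 for Hox D (6 genes) and -0.09 for Hox B (6 genes). The Pearson correlation was 0.53 for Hox A, 0.88 for Hox C, 0.40 for Hox D and 0.09 for Hox B. Correlations within clusters were not run under the alternatives. By cluster, the median was -0.29 for Hox A (percentile 0.48), -0.14 for Hox B (8.13), -0.05 for Hox C (21.1) and 0.32 for Hox D (97.1), while Hox C turned to 0.17 without _x_at and _s_at probe sets. Hox D was at 0.53 with the floor at the 60th percentile, above the range at percentile 99.8, at 0.19 with the mean over probe sets and at 0.11 with the floor at the 40th percentile. The calls of Hox A and of groups 1 to 4 as below the range were lost with the floor at the 60th percentile, with the mean over probe sets and without _x_at and _s_at probe sets, and the Hox A median turned to 0.01 and 0.04 under the latter pair.

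**Figure D3:**
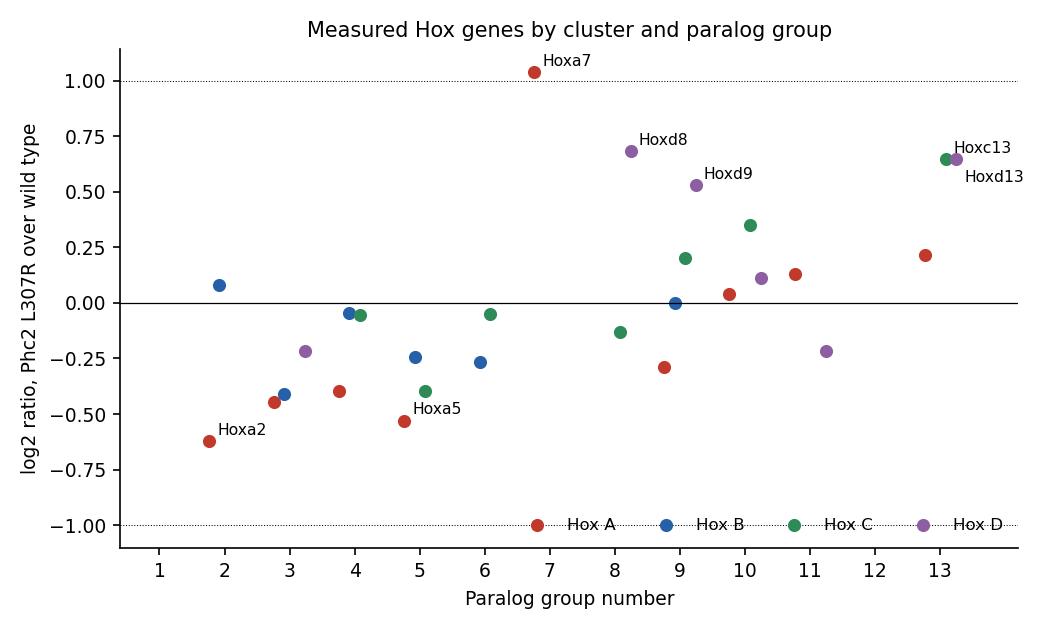
Each point is 1 of 28 measured Hox genes, with its paralog group number on the x axis, its log2 ratio of Phc2 L307R over wild type on the y axis and its cluster as colour; dotted lines mark a 2-fold difference. Genes of groups 1 to 4 lie mostly below 0 (median -0.31) and those of groups 9 to 13 mostly above (median 0.17), and Hoxa7 lies highest at 1.04.

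Transcription factors of development that are typical Polycomb targets in other cells were higher as a list. Of 169 with a probe set, 81 were measured, 57 of them higher in Phc2 L307R, with a median log2 ratio of 0.18 at percentile 99.86. Centred ratios gave 0.12. Of the 81, 71 already lay above the floor in wild type, and 31 also stand in other lists. The members not measured lay below the floor on both arrays, so the median mostly describes genes with signal in wild type and does not show a loss of silencing. At least 2-fold higher were Vax2, a factor of the ventral retina (at least 1.44 on the log2 scale), Dlx5, a homeobox factor of bone and limb (1.15), and Gata2, a factor of blood and endothelial cells (1.04). Emx1, a cortical homeobox factor, was lower at -1.01. Markers of cartilage and bone were higher on the same array, Dlx5 among them. Signalling genes of the same kind had a median of 0.13 over 35 measured members (percentile 87.5), with Gdf10 at 1.17 and Bmp2 at -1.14. Limb and trunk transcription factors, all 23 of whose measured members also stand in other lists, had a median of 0.23 (percentile 97.9), with Tbx5 at 0.61 and Meis2 at -0.95. That call was lost under 4 alternatives: loess, a floor at the 40th percentile, no floor and the mean over probe sets.

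The subunits of both Polycomb complexes lay inside the range of random lists as lists, PRC2 near its lower end. The 23 measured PRC1 subunits had a median log2 ratio of 0.05 (percentile 43.4), which was -0.02 in centred ratios, with Cbx8 at 0.78, Phc1 at 0.59, Phc3 at 0.25 and Bcor at -0.43. The 12 PRC2 subunits had a median of -0.12 (percentile 3). It lay below the range with the pseudocount (percentile 2.21) and, in an alternative chosen after seeing the data, without the neighbours of Phc2 (-0.22, percentile 0.805). It was -0.02 with the floor at the 60th percentile and without _x_at and _s_at probe sets. Ezh2, the methyltransferase of PRC2, was at -0.66 and Mtf2 at -0.52, while Ezh1 was at 0.56 and Epop at -0.63 or lower.

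The Ink4a and senescence list, which holds cyclin-dependent kinase inhibitors and secreted factors, lay above the range, though no member differed 2-fold. It had a median log2 ratio of 0.33 over 16 measured members, 11 of them higher, at percentile 99.96. Of the 16, 8 also stand in other lists. Cdkn2a, which encodes p16Ink4a and p19Arf and is a Polycomb target in fibroblasts, lay below the floor on both arrays, with signals of 47 in wild type and 91 in Phc2 L307R. Cdkn2b was at 0.60, Cdkn2c at 0.67, Cdkn1a at 0.67 (0.50 at its other probe set), Cdkn1c at 0.55 and the collagenase Mmp13 at 0.94. Targets of p53 had a median of 0.12 over 18 genes, 16 of them higher (percentile 80.1, and 98.0 with the mean over probe sets), with Btg2 at 0.62 and Sesn2, a neighbour of Phc2, at 0.60.

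Both cell cycle lists lay below the range. The S phase list had a median log2 ratio of -0.24, with 24 of 29 genes lower and the median at percentile 0 of the random lists. Ccne2 (cyclin E2) was at -0.91, the DNA polymerase subunit Pola1 at -0.60 and Uhrf1, which maintains DNA methylation at replication, at -0.57. The G2 and M phase list had a median of -0.21, with 26 of 29 genes lower (percentile 0.01). The kinetochore protein Nuf2 was at least 2-fold lower at -1.08, Kif2c, a neighbour of Phc2, was at -0.72 and Birc5 (survivin) at -0.54. Both calls held under all 10 alternatives run on lists. Centring is 1 of these and cannot change a call, since it shifts a list and its random lists alike. The G2 and M phase median was also -0.21 with the floor at the 40th or 60th percentile and without a floor, so these alternatives test its call little.

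Extracellular matrix genes of fibroblasts were higher as a list. Of 33 genes, all measured, 29 were higher, with a median log2 ratio of 0.40 at percentile 100; quantile normalization gave 0.23, still above the range. At least 2-fold higher were Fbln1 (fibulin 1, 1.07), Eln (1.05) and Lum (lumican, 1.03), and Mfap5, a microfibril protein, was at 0.99. Genes of matrix remodelling had a median of 0.25 over 20 measured members (percentile 99.69), with Mmp13 at 0.94 and Timp3, an inhibitor of metalloproteinases, at 0.70. Targets of TGF-beta had a median of 0.22 over 20 genes, 16 of them higher (percentile 99.38), with Itgb5 at 0.44 and Tagln at 0.42.

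Cartilage markers were higher on the same array. Of 18 chondrocyte markers with a probe set, 16 were measured and 15 were higher, with a median log2 ratio of 0.70 at percentile 100. Matn1 (at least 1.62), Col11a2 (1.31), Snorc (1.11), Hapln1 (1.04) and Comp (1.02) differed at least 2-fold, the abundant Col2a1, the main cartilage collagen, was at 0.49 and Acan (aggrecan) at 0.75. Sox9, the master regulator of cartilage, was at -0.29. Col2a1 and Acan, outside the rule for named genes, were fixed by name as markers before the data were seen, while Comp and Sox9, and Omd among the osteoblast markers, were chosen after their values were seen. Matn1 is also 1 of the neighbours of Phc2. With a floor at the 60th percentile the median was 0.43, still above the range. Of 8 osteoblast markers 5 were measured, with a median of 0.72 (percentile 99.91): Ibsp at 2.12, Dlx5 at 1.15, Alpl (alkaline phosphatase) at 0.72, Sp7 at 0.50 or more and Omd at -0.33. That call was lost with the floor at the 60th percentile, at a median of 0.37. Alpl, whose value is the main median of this list, also lay on the chromosome of Phc2, 112 measured genes from it on the side of higher position.

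Other cell types differed less. Macrophage markers had a median of 0.56 over 8 measured of 18 (percentile 99.91), with Laptm5 at 1.00, Csf1r at 0.57 and Lyz2 at 0.57; Laptm5 had a signal of 256.0 in Phc2 L307R, and a second measured probe set of this gene, a neighbour of Phc2, gave -0.06 or lower. C1qa, fixed by name as a marker before the data were seen, lay below the floor on both arrays, as did Ptprc, chosen after its values were seen, and the call was lost with the floor at the 60th percentile and without _x_at and _s_at probe sets. Smooth muscle and pericyte markers had a median of 0.31 over 14 measured members (percentile 99.79), with Myh11 at 0.71 and Rgs5 at -0.64, and lost the call under quantile normalization, at percentile 97.47. Skeletal muscle markers had a median of 0.01 over 21 measured members (percentile 24.04), which turned below 0 with loess, centring and the mean over probe sets. The medians of the other marker lists lay inside the range: tendon 0.26 (6 measured), adipocyte 0.04 (4), endothelium 0.05 (7), neuron -0.02 (9), neural progenitor -0.06 (5), glia 0.11 (6), epithelium 0.06 (7), mesothelium 0.01 (6), kidney and gonad mesenchyme -0.04 (7) and erythroid 0.29 (1), though several turned sign. Those of adipocyte, endothelium, epithelium and mesothelium turned below 0 with centring, that of endothelium with the floor at the 60th percentile, and those of glia and mesothelium with the mean over probe sets. Those of neuron and neural progenitor turned above 0 with the floor at the 60th percentile, and that of neural progenitor with the floor at the 40th percentile too. No hepatocyte marker was measured. Single members that differed at least 2-fold were Emcn (endothelium, -1.15), Map2 and Stmn2 (neuron, -1.31 and 1.01) and Sfn (epithelium, at least 1.42), the last a neighbour of Phc2.

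**Figure D4:**
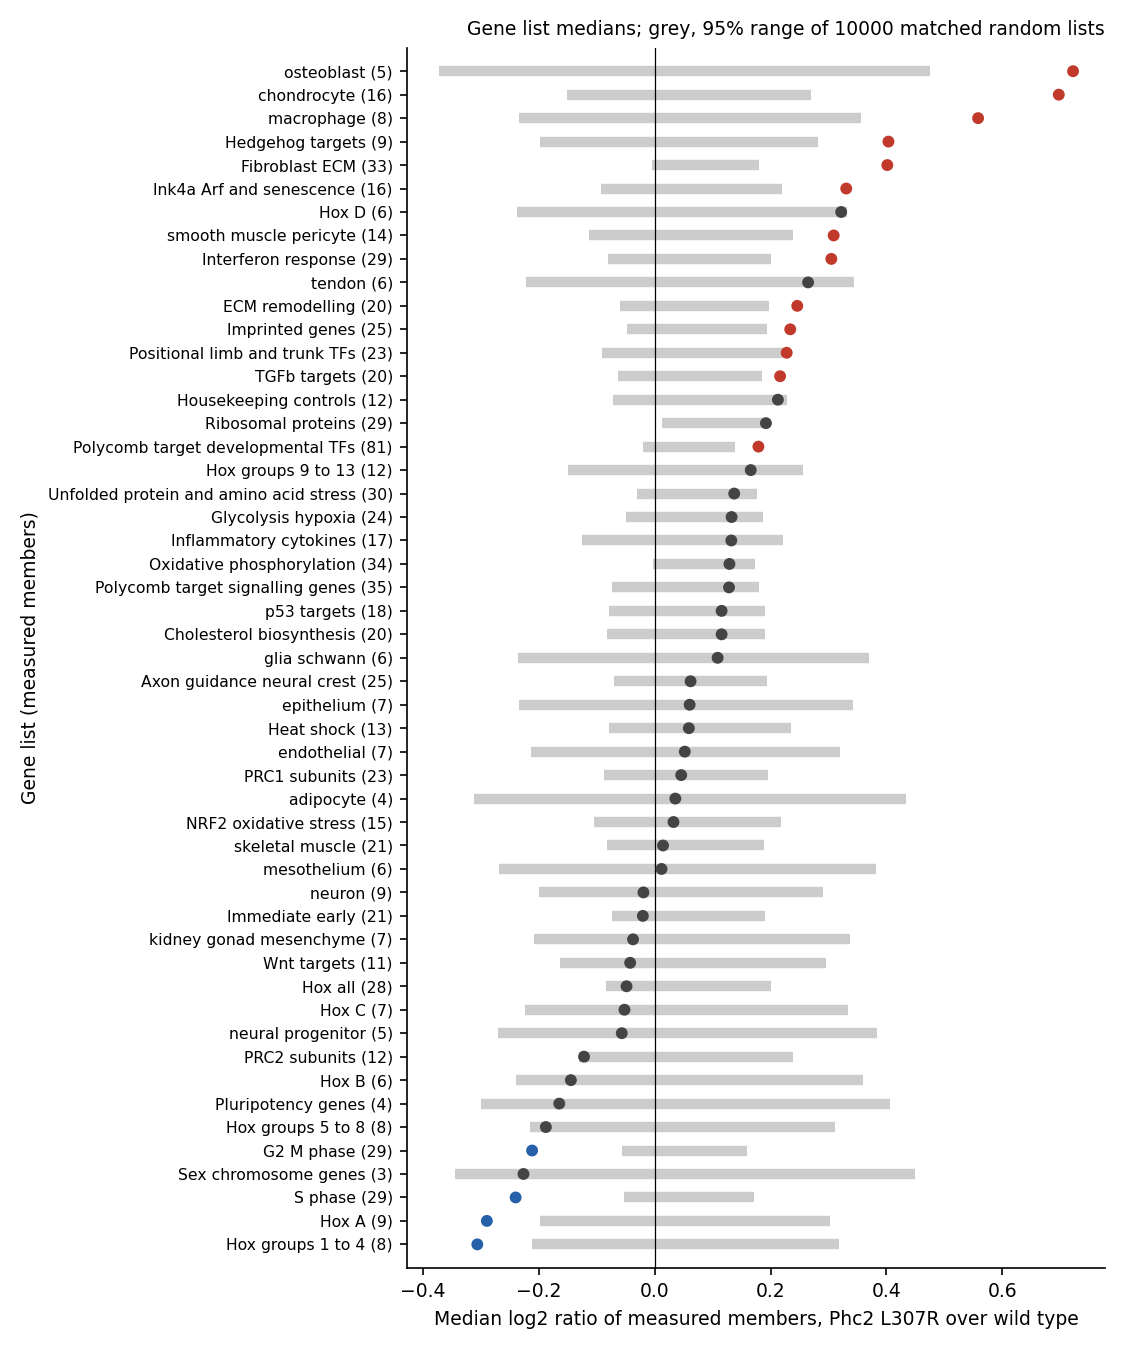
Each point is the median log2 ratio of Phc2 L307R over wild type (x axis) of the measured members of a gene list (y axis, number measured in parentheses, lists with at least 3), and the grey bar is the 95% range of 10000 matched random lists. Red and blue points lie above and below the range; osteoblast (0.72) and chondrocyte (0.70) markers lie highest, Hox groups 1 to 4 (-0.31) lowest, and the ribosomal list, at 0.19, turned to -0.05 under quantile normalization.

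Of the remaining lists, those of interferon response, Hedgehog targets and imprinted genes were above the range. Interferon response genes had a median log2 ratio of 0.30 over 29 measured members, 23 of them higher (percentile 99.96; 0.47 without a floor), with Ifit1 at 1.21, Ifi27 at 0.93 and Tap1, a peptide transporter, at 0.92. The Hedgehog list, which holds pathway components beside targets, had a median of 0.40 over 9 genes (percentile 99.81), 5 of them also in other lists. Gas1 was at 0.96, Osr2 at 0.91 and Hhip at 0.71. The call of this list was lost with the pseudocount and with the mean over probe sets. Whether the pathway was more active was not tested. Imprinted genes had a median of 0.23 over 25 genes, 20 of them higher (percentile 99.56), with Dcn (decorin) at 0.88 and Igf2r at 0.62, and lost the call with the mean over probe sets.

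The other lists lay inside the range. Medians above 0 were those of inflammatory cytokines (0.13 over 17 genes), cholesterol synthesis (0.12 over 20), glycolysis and hypoxia (0.13 over 24), unfolded protein and amino acid stress (0.14 over 30), heat shock (0.06 over 13), NRF2 and oxidative stress (0.03 over 15), oxidative phosphorylation (0.13 over 34), housekeeping controls (0.21 over 12), ribosomal proteins (0.19 over 29) and axon guidance (0.06 over 25), though those of heat shock, NRF2 and axon guidance turned below 0 with centring, those of NRF2 and ribosomal proteins under quantile normalization, and those of heat shock and NRF2 with the mean over probe sets. Sema3f, of the axon guidance list, was at least 2-fold higher at 1.10. Medians below 0 were those of immediate early genes (-0.02 over 21 genes), Wnt targets (-0.04 over 11), pluripotency genes (-0.16 over 4) and sex chromosome genes (-0.23 over 3), though that of immediate early genes turned to 0.05 with the mean over probe sets and without _x_at and _s_at probe sets, and that of pluripotency genes to 0.04 with the floor at the 40th percentile. Of 19 germline genes with a probe set, 1 was measured, Asz1 at 0.14 or more. In all, 53 lists had a measured member, 13 lay above the range and 4 below. By chance 2.65 would lie outside if the genes of a list varied independently, as in the random lists. Genes of 1 list can vary together between any 2 cultures, so the excess over 2.65 does not measure an effect of the genotype. Of the 17 lists outside the range, 9 kept their call under all 10 alternatives, though centring, 1 of these, cannot change a call. Lists also share members.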

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

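H2-D1 and H2-K1 lie outside the rule for named genes and were chosen after their values were seen. The tests on H2-D1 in this part were chosen after its values were seen, apart from the comparison with other genes that have as many probe sets. Probe sets that name several genes or none took no part in the comparison of genes. Among the 2878 of them above the floor on at least 1 array, 2324 of them with no gene listed, 17 were at least 2-fold higher in Phc2 L307R and 30 at least 2-fold lower. The lowest were 1445226_at, with no gene listed (at least 11.0-fold lower, 1047 in wild type and 50.4 in Phc2 L307R), a probe set shared by Ifi211 and Ifi205 (at least 5.29-fold lower), and one shared by H2-K1 and H2-D1 (4.45-fold lower). The highest were 1455892_x_at, with no gene listed (3.69-fold higher), and a probe set shared by the Ugt1a genes (3.28-fold higher). These probe sets were chosen after their values were seen, and no explanation was tested for them.

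Probe sets of H2-D1, a classical class I histocompatibility gene, differed in opposite directions: of 7 measured, 3 were at least 2-fold higher in Phc2 L307R (2.10-fold, 2.09-fold and 2.22-fold) and 3 at least 2-fold lower (at least 7.30-fold, 5.80-fold and 8.13-fold). A change in the level of 1 transcript alone would move all of them in 1 direction, and the 3 lower beside the 3 higher argue against it. Of the 42 other genes with as many measured probe sets 0% had as wide a range of log2 ratio as the 4.17 of H2-D1, though H2-D1 was singled out for this range, the second widest of 5460 genes. With log2 ratios shuffled between probe sets of similar signal and every gene searched, 0 of 1000 shuffles gave any gene 3 probe sets 2-fold higher and 3 lower, which argues against independent noise of single probe sets. Different H2 haplotypes in the 2 cultures are a candidate explanation, which would conflict with the single strain in the labels. The range of H2-K1, 2.66, was reached by 0.388% of 2322 other genes, but this test was chosen with its values in view and gives no support. For a wide stretch of other DNA, the median range between probe sets of 1 gene among the 200 neighbours of H2-D1 stood at percentile 72.6, below the 90th percentile that the test set as counting against it. The count of neighbours at least 2-fold different, 5, stood at percentile 93.3. A few altered genes among the 77 under that median move it little, and the share that strain variants would alter is not known without probe sequences, so such a stretch stays open. Cross-hybridisation with other class I genes cannot be told apart from these, since only 1 measured H2-D1 probe set lacks the suffix _x_at, and the genotype itself remains untested as a cause with 1 culture each.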

How the results depend on the processing

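No paired analysis was possible because each genotype has 1 array, and for the same reason no array could be left out. The removal of the neighbours of Phc2 was chosen after seeing the data. The counts of genes at least 2-fold higher and lower, 66 and 61 as reported, were 479 and 371 at 1.5-fold, 8 and 6 at 3-fold, 159 and 122 without a floor, 27 and 35 with the floor at the 60th percentile, and 26 and 22 with the pseudocount; the floor at the 40th percentile gave 127 higher. The genes with every one of at least 2 probe sets past the threshold, 5 as reported, were 45 at 1.5-fold, 2 at 3-fold, 8 without a floor, and 3 with centring and 3 with the pseudocount. Hox genes past the threshold in the higher direction, 1 as reported, were 4 at 1.5-fold, 2 with the floor at the 40th percentile and 2 without a floor, and 0 at 3-fold, with centring, with the floor at the 60th percentile and with the pseudocount. The cause of these changes was not tested.

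Centring on the median of measured genes moved the median log2 ratio of the S phase list to -0.30, of the G2 and M phase list to -0.27, of Polycomb target transcription factors to 0.12 and of fibroblast matrix genes to 0.34. The matrix list was at 0.32 with loess, 0.27 with the mean over probe sets and 0.23 under quantile normalization. Polycomb target transcription factors were at 0.23 without a floor, and the Ink4a and senescence list at 0.25 with the pseudocount. Chondrocyte and osteoblast markers were at 0.43 and 0.37 with the floor at the 60th percentile and at 0.51 and 0.43 with the pseudocount. The Hox A median reversed to 0.0102 with the mean over probe sets and to 0.0408 without _x_at and _s_at probe sets; the cause was not tested, nor for the other medians. Of 518 list medians under alternatives, 52 moved and 2, both of Hox A, were counted as reversed. Further medians changed sign without being counted so, among them that of ribosomal proteins, from 0.19 to -0.05 under quantile normalization. Of 234 values of named genes, 222 stayed at least 2-fold, 26 moved by at least the spread between probe sets and 0 reversed. Zfp593 was at 0.03 without _x_at and _s_at probe sets. With the floor at the 60th percentile, 2-fold was no longer reached by Cnmd (0.80), Matn1 (0.72), Tle6, Tspan11, Pianp, Efcab3, Dmxl1 and Aunip. Pianp and Dmxl1 also fell short with the pseudocount, and Vegfd with the mean over probe sets. Dim genes are limited by the floor, 94.8, near which a fold is only a bound.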

Other observations

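The tests on chance placement near Phc2 and on the share of fibroblasts, and the split of the neighbours by side, were chosen only after the results were seen. A clone-named gene, AI506816, outside the rule for named genes, had a signal of 1340 in wild type and 24.7 in Phc2 L307R at its only probe set, at least 14.1-fold lower, the second strongest difference after Cap1, and was chosen after its values were seen.

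Many genes with a 2-fold difference lay near Phc2, 10 of the 200 neighbours, 9 of them on 1 side, where 5 more lay farther out. The count stood at percentile 100 of those around other genes, which argues against chance placement. The weight of that percentile is limited, since the sets of neighbours around other genes overlap widely. At 1.5-fold it was less clear, with 25 neighbours at percentile 97.6 against a median of 15 and a highest count of 30 elsewhere. The count was taken at the main floor and probe set rule only. Under others some of the 10 fall short of 2-fold. Zfp593 was at 0.03 without _x_at and _s_at probe sets. With the floor at the 60th percentile Matn1 was at 0.72 and Aunip at -0.52. The median log2 ratio of the neighbours, 0.0835 (0.11 on the side with 9), argues against the gain or loss of a copy of the region. Linked DNA of another mouse strain, carried along with the mutated allele, could alter single probe sets, although the labels give C57BL/6 for both cultures: the median range between probe sets of 1 gene among the neighbours stood at percentile 69.3, below the 90th percentile set in advance as counting against it. That bound was ill chosen, since the median covers 94 genes of which 4 belong to the pattern and moves little with these, a point made after the value was seen, so linked DNA cannot be told apart from effects of the genotype. The 2 probe sets of Cap1 differed alike, at -4.54 and -4.98, and those of Ptp4a2, chosen after its values were seen, from -1.74 to 1.07.

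Cartilage and bone markers were higher in Phc2 L307R. Markers below the floor in wild type do not account for this, since the 18 markers above it there had a median log2 ratio of 0.68 at percentile 100 of matched lists. Signals a little above the floor can account for part of the size: with the floor at the 60th percentile the medians of both marker lists were lower. The chondrocyte list then stayed above the range, while the osteoblast list lost its call. A lower share of fibroblasts, which would raise the markers of every other cell type alike, would go with the macrophage and smooth muscle markers at percentiles 99.91 and 99.79. The skeletal muscle markers, at percentile 24.04, argue against such a rise in every cell type. The higher fibroblast matrix genes do not decide it, since their level within the fibroblasts may differ too. For a larger share of cartilage cells in the mutant culture, the test was the share of measured chondrocyte markers that were higher, 93.75%, which restates the pattern and supports nothing. Such a share and a change within the fibroblasts, through the genotype or otherwise, cannot be told apart with 1 culture per genotype.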
